A study of Homo sapiens with 36 samples.

How the data were processed

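The series followed the H7 human embryonic stem cell line, an established line, through directed differentiation toward endoderm. Of its 36 samples, 6 were RNA-seq libraries, with 1 library for each of 6 stages, and 30 were ChIP-seq samples (an input and 4 histone marks at each stage), which were not analysed here. Each library was placed in its stage by its title. For several samples, including the PFG and MHG RNA libraries, another label field named a different gut region from the title, so the stage names rest on the titles.

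The deposited values were FPKM (fragments per kilobase of transcript and per number of mapped fragments) per gene, with a lower and an upper confidence bound and a status for each, per the file headers. The submitters' processing notes name TopHat, Cufflinks and the human genome build hg19 and give no versions. The RNA kit named in the labels' protocols was a TruSeq RNA kit. The labels used here do not state that strand was used in counting, so reads from a gene and an overlapping or antisense neighbour are treated as inseparable. All 6 tables held the same 24004 rows in the same order, with 22761 distinct gene symbols, of which 291 had more than 1 row. Where a symbol had several rows, the row on the main chromosome was used for that gene, and 1260 rows lay on alternate contigs. Coordinates are hg19 gene spans as deposited, with starts counted from 1.

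The total number of fragments per library was not given in the sources used here. The deposited bounds allowed the libraries' relative depth to be estimated. If the upper bound lies 2 SD above the FPKM and the error is that of counting, each value implies a number of fragments. Among genes with 0.5 to 30 implied fragments, between 52.0% and 53.9% of these numbers lay within 0.03 of a whole number, where an even spread would give 6%. Relative to the ESC library, the depth so estimated was 1.29 for APS, 1.22 for DE, 1.27 for AFG, 1.27 for PFG and 1.28 for MHG. The distance from the FPKM to the upper bound had a median of 11.5% to 13.4% of the FPKM among genes between 1 and 2 FPKM, and of 3.66% to 4.16% among genes between 10 and 20 FPKM. These bounds cover counting and assignment error only. They hold nothing about the spread between cultures, which 1 library per stage cannot show.

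FPKM values are not counts, so no count model was fitted, and with 1 library per stage no test and no p-value was computed. Differences were taken as log2(FPKM + 1) in one library minus the same in the other, a scale that understates the difference of low genes. A gene entered a comparison with an FPKM of 1 or more in either library, and was counted as higher or lower with a difference of at least 1 on the log2 scale, which is 2-fold. The 8 comparisons were APS against ESC, DE against APS, each of AFG, PFG and MHG against DE, and the 3 day 7 libraries against each other. A gene marked a library when it had an FPKM of 5 or more there and lay at least 2 log2 units (4-fold) above each of the other 5 libraries. Rows that Cufflinks had marked as failed or as holding too much data in either library were left out of a comparison, a step not among the choices fixed before the data were examined. This affected 14 to 41 failed rows per library and 1 row with too much data, FN1 in PFG. Standard errors (SE) of single differences were propagated from the deposited bounds.

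Before the data were examined, 26 gene lists were fixed. They covered pluripotency, primitive streak, mesoderm, blood and endothelium, definitive endoderm, anterior foregut, posterior foregut, mid-hindgut, HOX paralogues 1 to 4, 5 to 9 and 10 to 13, neural and neural crest, extraembryonic, hepatic, pancreatic, and fibroblast and stroma genes. The others were the retinoic acid, WNT, BMP, NODAL and TGF-beta, and FGF and ERK responses, epithelial and mesenchymal transition genes, cell cycle, stress and immediate early genes, and housekeeping genes. Some genes stand in more than 1 list. For each list and comparison, members with an FPKM of 1 or more in either library were called measured, and those at least 2-fold higher or lower were counted. A member measured through only 1 of the 2 libraries could not be counted the other way. Such counts describe the libraries and test nothing. The median difference over all members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The list with the highest and the list with the lowest median in each comparison are given with their medians.

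The genes named are members of those lists, the 10 with the largest positive and the 10 with the largest negative difference in each comparison, and the 10 leading marking genes of each library. The last 3 groups needed an FPKM of 5 or more and a symbol with 1 row, and left out symbols that start with SNOR, MIR, SCARNA, RNU, RNA5, RNY, LOC or LINC, XIST, Y-linked genes and rows marked as failed. The rule goes by the start of the symbol, so U58, a row of a small nucleolar RNA, and C12orf39 also met it, and neither is given a value. Genes named outside this rule were chosen after their values were seen, and stand only in the closing section. Some genes that met the rule are not reported here by name, though they remain in the counts and medians. A further 9 lists, on p53 targets, DNA replication, metallothioneins, basement membrane, cholesterol synthesis, glycolysis and hypoxia, serine and ATF4, IGF binding, and yolk sac endoderm, were written after the main results were seen.

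The alternatives tried were pseudocounts of 0.1 and 3, an FPKM minimum of 5 or none, rescaling each library by the median of its ratios to the geometric mean, rescaling each library to a sum of 1000000 FPKM, which also multiplies every value against the pseudocount and the FPKM minimum, a 4-fold threshold, only genes whose deposited intervals do not overlap, and rows of a symbol summed. Keeping failed rows, taking list medians over measured members, and rescaling each library to the mean of the library sums, which changes the scaling alone, were added after the data were seen. The counting was tested on simulated data: 2 libraries were drawn from the APS values with the implied counting noise and 200 genes changed. The FPKM minimum was met by 12550 genes, of which 12351 were unchanged, and 1 changed gene did not meet it and was not recovered. All 50 genes raised 3-fold and 49 of the 50 lowered 3-fold were recovered, and 96 of 12351 unchanged genes (0.777%) passed the 2-fold threshold from counting noise. The computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.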

Results

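RNA-seq profiled gene expression at 6 stages of endoderm differentiation from H7 human embryonic stem cells, with 1 library per stage. The undifferentiated cells (ESC) were followed by anterior primitive streak (APS), reached after 24 hours with 100 ng/mL Activin, 2 µM CHIR99021, a GSK3 inhibitor that activates WNT signalling, and 50 nM PI-103, a PI3K and mTOR inhibitor. Definitive endoderm (DE), the precursor of the gut lining, followed on day 3 after a further 48 hours with 100 ng/mL Activin and 250 nM of the BMP receptor inhibitor LDN-193189, with FGF2 optional. From DE, 3 media were applied for 4 days, giving libraries on day 7. Anterior foregut (AFG) received 1 µM A-83-01, a TGF-beta and NODAL receptor inhibitor, with 250 nM LDN-193189. Posterior foregut (PFG) received 2 µM retinoic acid with 250 nM LDN-193189. Mid-hindgut (MHG) received 10 ng/mL BMP4, 3 µM CHIR99021 and 100 ng/mL FGF2.

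Between 12510 and 13023 rows per library had an FPKM of 1 or more. Estimated depth was lowest for ESC and between 1.22 and 1.29 times as high in the others. Across 14801 genes, the Pearson correlation of log2(FPKM + 1) was highest between ESC and APS (0.92) and lowest between ESC and PFG (0.85), where genes are not independent replicates. The difference of any stage from another carries no replicate check, and intervals given with values are the deposited ones, which cover counting and assignment error.

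**Figure D1:**
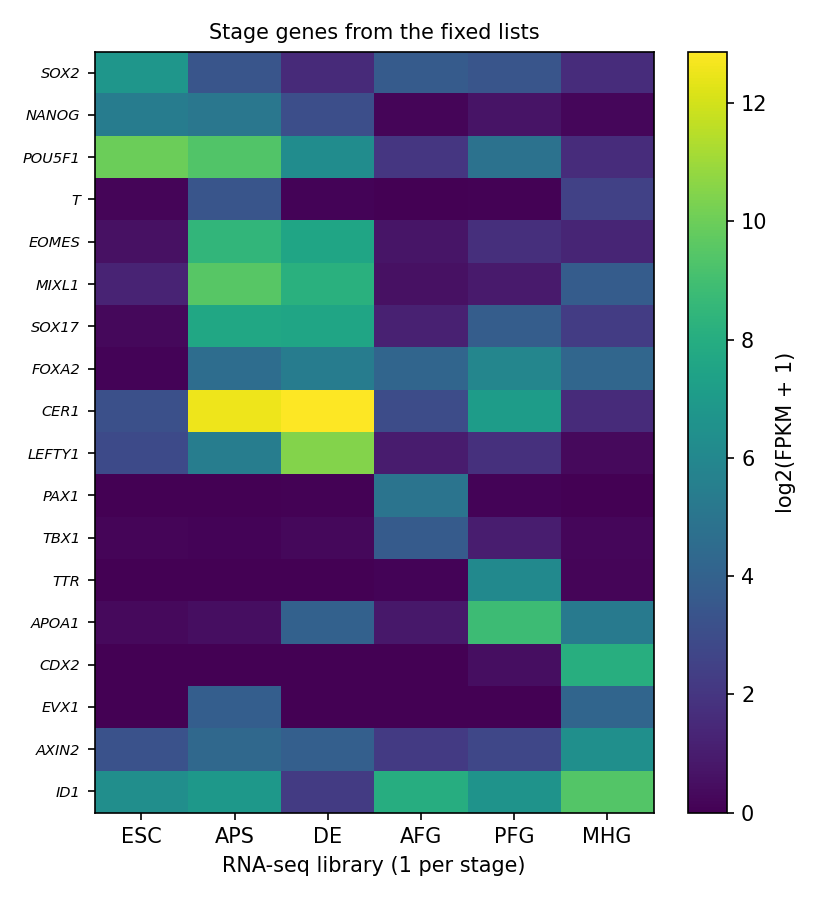
Expression of 18 genes from the fixed lists in the 6 libraries, as log2(FPKM + 1) by colour, with 1 column per library. SOX2 had its highest value in ESC, CER1 in DE, PAX1 in AFG, TTR in PFG, and CDX2 in MHG.

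The comparison of APS with ESC asks what 24 hours of streak induction did to the stem cell profile. All 16 members of the primitive streak list were higher in APS, with a median difference of 6.07, above all 10000 matched random lists. EOMES, a T-box transcription factor of the streak and early endoderm (chromosome 3, 27757886 to 27763785), stood at 0.49 FPKM in ESC (0.39 to 0.60) and 351 in APS (349 to 354). MIXL1, a homeobox gene of the streak, stood at 1.46 and 744 FPKM, and GSC at 0.20 and 150. The streak gene T (brachyury) reached 9.60 FPKM. Of 14 measured definitive endoderm genes, 12 were higher, among them SOX17, a transcription factor of endoderm (0.21 FPKM in ESC, 205 in APS). CER1, which encodes a secreted antagonist of NODAL, BMP and WNT ligands, had the largest difference of all named genes here, from 7.94 to 6083 FPKM (log2 difference 9.41 ± 0.05 SE).

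The pluripotency list had the lowest median, −0.51, below all random lists, with 6 of 16 measured members lower and 1, GDF3, higher. SOX2 was lower by 3.37 log2 units, at 109 FPKM in ESC (108 to 111) and 9.64 in APS (9.21 to 10.1), while POU5F1 remained at 665 FPKM against 996 and NANOG at 33.3 against 42.1. The leading lower genes included HES3 (40.6 and 0.71 FPKM) and IDO1 (48.9 and 1.48). WNT response genes were higher for 8 of 12 measured members, led by DKK4, a WNT antagonist (0.92 and 921 FPKM), and NODAL and TGF-beta response genes for 9 of 13, with 1 lower and NODAL itself at 2.71 and 185 FPKM. BMP response genes were higher for 5 of 9, and FGF and ERK response genes for 4 of 14, with 1 lower. Among mesenchymal transition genes, 6 of 10 were higher, including CDH2 (N-cadherin, 8.82 and 125 FPKM), and among epithelial genes 1 of 12 was higher and 4 were lower, including CDH1 (E-cadherin, 87.7 and 23.4 FPKM). None of the 17 cell cycle genes and none of the 12 housekeeping genes differed 2-fold. In all, 673 genes were higher and 1195 lower among 13497. With a pseudocount of 3 the lower count was 592, and with an FPKM minimum of 5 it was 759.

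The comparison of DE with APS covers the following 48 hours, in which CHIR99021 and PI-103 were withdrawn and the BMP receptor inhibitor added. The definitive endoderm list had the highest median, 1.33, above all random lists, with 10 of 17 members higher and none lower. CXCR4, a chemokine receptor of definitive endoderm, stood at 24.6 FPKM in APS (23.7 to 25.5) and 634 in DE (629 to 638), and FOXA1 at 0.24 and 4.69. SOX17 was 205 in APS and 192 in DE. LEFTY2 and LEFTY1, NODAL antagonists with similar sequences whose reads may not be fully separable, were at 3188 and 1446 FPKM in DE against 13.3 and 43.3 in APS. NODAL was at 185 in APS and 196 in DE, and 3 of 13 genes of its response list were higher. Pluripotency genes were lower for 9 of 14 measured members, including POU5F1 (665 and 75.5 FPKM), whereas LIN28A stayed at 371 and 358 FPKM and SALL4 at 62.6 and 73.3.

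The cell cycle list had the lowest median, −1.49, below all random lists, with 15 of 17 members lower in DE. CCNB1 (cyclin B1) stood at 129 FPKM in APS (127 to 131) and 39.8 in DE (38.8 to 40.8), and MKI67 at 21.1 and 8.46. Of 12 housekeeping genes, HPRT1 was lower (38.8 and 11.7 FPKM). BMP response genes were lower for 7 of 9, with ID1, a direct BMP target, at 117 and 3.65 FPKM, and WNT response genes were lower for 6 of 14 and higher for 1, with DKK4 at 921 and 22.4 FPKM. Streak genes were lower for 6 of 16, among them T (9.60 and 0.08 FPKM) and EVX1 (13.5 FPKM and listed at 0), and 1 was higher. EOMES was at 351 FPKM in APS and 186 in DE. Of 9 measured mesoderm genes 1 was higher and 3 were lower, led by PDGFRA (22.6 and 0.62 FPKM). CDH1 was at 2.60 FPKM in DE, while the keratin genes KRT8 and KRT18 were at 1525 and 1179, and 6 of 11 epithelial genes were higher and 3 lower. Stress and immediate early genes were higher for 5 of 14, including ATF3 (10.8 and 50.9 FPKM). In all, 1290 genes were higher and 923 lower among 13341. Under median-ratio scaling the split was 1556 and 720 and with libraries rescaled to their mean sum 1529 and 707, so that the share of higher genes was 68.4% under both against 58.3%, and with a pseudocount of 3 the counts were 816 and 600.

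The 3 day 7 libraries were each compared with the same DE library, so any peculiarity of that library enters all 3 comparisons. The day 7 media listed no Activin, which the DE step had held at 100 ng/mL, and were applied for 4 more days. No day 7 control in the DE medium was among the libraries. These shared changes therefore cannot be told apart from the factors of each medium. The median gene was 0.16 higher in AFG and 0.12 higher in MHG than in DE on the log2 scale, and differences there are to be read relative to that shift. Median-ratio scaling removed it (0.00 and −0.03). Some lists went the same way in all 3. The NODAL and TGF-beta response, primitive streak and definitive endoderm lists had medians below all random lists in each. The BMP response list had medians of 2.21, 0.98 and 3.32 in AFG, PFG and MHG, each above the middle 95% of random lists. Other lists leaned the same way by counts of members. Pluripotency genes were lower for 8 of 14 measured members in AFG, 9 of 15 in PFG and 7 of 14 in MHG, with 1, 2 and 2 higher. FGF and ERK response genes were lower for 6, 6 and 5 of 14, with 1, 2 and 2 higher. Extraembryonic genes were higher for 6 of 8 measured members in AFG, 4 of 6 in PFG and 5 of 7 in MHG, with 1 lower in each of PFG and MHG. Of the 15 extraembryonic genes, 2 reached 1 FPKM in DE, so most measured members entered through a day 7 library. Such members could not have been lower. Among them CGA stood at 0.05 FPKM in DE and at 30.0, 10.9 and 11.5 in AFG, PFG and MHG, and GATA3 at 0.36 and at 10.4, 7.31 and 12.7. GATA3 also stands in the BMP response list. Epithelial genes were higher for 5, 4 and 4 of 12, with 1 lower in MHG. The median lay inside the middle 95% of random lists for extraembryonic genes in PFG (0.07) and for epithelial genes in MHG (0.36).

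AFG against DE covers 4 days in which A-83-01 was added and Activin was no longer listed, with LDN-193189 in both media. The anterior foregut list had the highest median, 2.46, above all random lists, with 11 of 13 measured members higher and 2 lower. PAX1 (chromosome 20, 21686297 to 21696620), a pharyngeal endoderm gene, stood at 0.04 FPKM in DE and 30.4 in AFG (29.6 to 31.1). EYA1 stood at 1.48 and 30.3, ISL1 at 0.07 and 21.8, TBX1 at 0.19 and 12.1, and PAX9 at 0.51 and 8.45. Leading genes outside the list included FABP7 (4.61 and 575 FPKM), GPC3 (13.9 and 1456) and VGLL2 (0.08 and 70.4). OTX2 was at 334 and 164 FPKM. Definitive endoderm genes were higher for 1 and lower for 15 of 17, including SOX17 (192 and 1.27 FPKM), and streak genes for all 12 measured.

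The NODAL and TGF-beta response list had the lowest median, −4.21, below all random lists. Of its 13 measured members 10 were lower and 2 higher, with NODAL at 196 and 0.47 FPKM and LEFTY2 at 3188 and 3.10. BMP response genes were higher for 7 of 10 and lower for 1, with ID1 at 3.65 FPKM in DE (3.15 to 4.16) and 256 in AFG (252 to 260), although the medium contained LDN-193189. WNT response genes were higher for 4 and lower for 7 of 14. Cell cycle genes were higher for 9 of 17. Of 8 measured mesoderm genes 2 were lower and 6 were higher, including FOXC1 (2.12 and 12.8 FPKM), KDR (6.45 and 30.1) and TWIST1 (2.13 and 12.6). Neural and neural crest genes were measured for 3 of 18 members, of which 1 was higher and 2 lower, with SIX3 at 9.36 FPKM in AFG. None of the 39 HOX genes in the 3 lists reached 1 FPKM. In all, 1422 genes were higher and 1274 lower among 13755. Median-ratio scaling gave 1111 and 1536, which lowered the share of higher genes from 52.7% to 42.0%, whereas the mean sum gave 1516 and 1249 (54.8% higher), and a pseudocount of 3 gave 819 higher.

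PFG against DE covers 4 days in which retinoic acid was added and Activin was no longer listed, with LDN-193189 in both media. The retinoic acid response list had the highest median, 2.06, above all random lists, with 9 of 12 measured members higher. The AFG medium listed no retinoic acid, and the list median there against DE was 0.61, with 5 of 9 higher and 1 lower. In DE against APS it was 0.30, with 5 of 8 higher. Both lay above the middle 95% of random lists. CYP26B1, a retinoic acid hydroxylase, stood at 0.18 FPKM in DE and 43.9 in PFG (43.2 to 44.6), DHRS3 at 2.06 and 120, and RARB at 4.08 and 21.8. CYP26A1 was lower, at 1443 FPKM in DE and 368 in PFG. Of the 12 genes of HOX paralogues 1 to 4, 7 were measured and all 7 were higher. None of the 12 reached 1 FPKM in DE, so no measured member could have been lower. HOXB2 (chromosome 17, 46620019 to 46622393) stood at 23.4 FPKM in PFG and HOXB1 at 18.3. Of paralogues 5 to 9, HOXA5 was measured, at 3.06 FPKM, and of paralogues 10 to 13 none.

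All 9 measured hepatic genes were higher in PFG. Of 15 hepatic genes, 2 reached 1 FPKM in DE and 9 in PFG, so most entered the count through PFG. APOA1, an apolipoprotein of high density lipoprotein, stood at 15.3 FPKM in DE (14.2 to 16.3) and 449 in PFG (444 to 454), APOA2 at 135 and 828, and TTR (transthyretin) was listed at 0 in DE and at 67.7 in PFG. AFP reached 1.16 FPKM. Of 12 measured posterior foregut genes 5 were higher and 1 lower, and no gene of the pancreatic list reached 1 FPKM. The posterior foregut median was 0.25, inside the middle 95% of random lists. IGFBP3 (0.81 and 649 FPKM), IGF2 (6.26 and 1039), KRT7 (0.03 and 70.1) and TCF21 (listed at 0, and 56.2) were among the leading higher genes. IGFBP3 and KRT7 stand in the extraembryonic list. The IGF2 span overlaps 3 other rows, so its value may include their reads. Of 9 measured fibroblast and stroma genes 3 were higher and 1 lower, against 3 and 2 of 8 in AFG and 3 and 4 of 9 in MHG. The list median was 0.53 in PFG, above the middle 95% of random lists. It was 0.19 in AFG and −0.14 in MHG, both inside that range. The primitive streak list had the lowest median, −3.24, below all random lists, with 11 of 12 lower. Definitive endoderm genes were lower for 11 of 17 and higher for 2, while GATA4 was at 30.0 FPKM against 40.7 and FOXA2 at 58.6 against 41.3. None of the 17 cell cycle genes was higher and 1 was lower. NODAL and TGF-beta response genes were lower for 8 and higher for 3 of 13, WNT response genes lower for 7 and higher for 3 of 14, and BMP response genes higher for 6 and lower for 2 of 10. Stress and immediate early genes were higher for 4 of 14, including CDKN1A (7.72 and 129 FPKM) and MDM2 (10.5 and 59.7). In all, 1321 genes were higher and 1124 lower among 13735, with 826 higher under a pseudocount of 3. Median-ratio scaling gave 1232 higher and 1239 lower, and rescaling to the mean sum 1462 and 1038, so the excess of higher genes depended on the scaling. FN1 was listed at 0 in PFG with a mark for too much data and was not compared.

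MHG against DE covers 4 days with BMP4, CHIR99021 and FGF2, in a medium that listed neither Activin nor LDN-193189. The BMP response list had the highest median, 3.32, above all random lists, with 9 of 11 measured members higher. ID1 stood at 3.65 FPKM in DE and 693 in MHG (686 to 699), and MSX1 at 0.49 and 173 (171 to 175). WNT response genes were higher for 11 of 15 and lower for 1, with AXIN2, a negative feedback gene of the pathway, at 13.7 and 83.6 FPKM, NKD1 at 2.00 and 82.2, and LEF1 at 0.02 and 34.6. Among mid-hindgut genes 8 of 12 were higher and 2 lower. CDX2 (chromosome 13, 28536278 to 28543317), a caudal homeobox gene of intestine, was listed at 0 in DE and stood at 269 FPKM in MHG (267 to 272), and CDX1 was at 12.9. HOX genes were higher for 10 of 12 members in paralogues 1 to 4, for 14 of 15 in paralogues 5 to 9, and for 4 of 12 in paralogues 10 to 13, each count covering every member measured. None of these genes reached 1 FPKM in DE, so no measured member could have been lower. HOXB9 was listed at 0 in DE and at 142 FPKM in MHG, HOXC6 was at 48.1 and HOXB8 at 37.6. Several HOX spans overlap other rows, 2 of them for HOXC6, so their reads may be shared.

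The definitive endoderm list had the lowest median, −3.61, below all random lists, with 13 of 17 lower, including SOX17 (192 and 3.96 FPKM) and HHEX (52.7 and 0.04). NODAL and TGF-beta response genes were lower for 11 of 13 and higher for 1. CYP26A1 was at 1443 and 5.74 FPKM, and OTX2 at 334 and 3.18. Streak genes were lower for 11 and higher for 3 of 14 measured, the higher ones including EVX1 (listed at 0, and 17.7 FPKM) and T (0.08 and 4.62). Of 11 measured mesoderm genes 5 were higher, including TBX3 (0.63 and 45.2 FPKM) and MSGN1 (listed at 0, and 7.75), and 4 were lower, including KDR (6.45 and 0.59) and TBX20 (1.99 and 0.01). Blood and endothelium genes were measured for 3 of 12 members, with SOX7 higher (0.22 and 4.57 FPKM), SOX18 lower (16.7 and 0.72) and TEK at 0.89 and 2.63. Cell cycle genes were higher for 12 of 17, and stress and immediate early genes lower for 6 of 14 and higher for 1. In all, 1486 genes were higher and 1686 lower among 13631, with 948 higher under a pseudocount of 3. Median-ratio scaling gave 1158 and 1969 and the mean sum 1274 and 1833, and the share of higher genes was 37.0% and 41.0% against 46.8%.

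**Figure D2:**
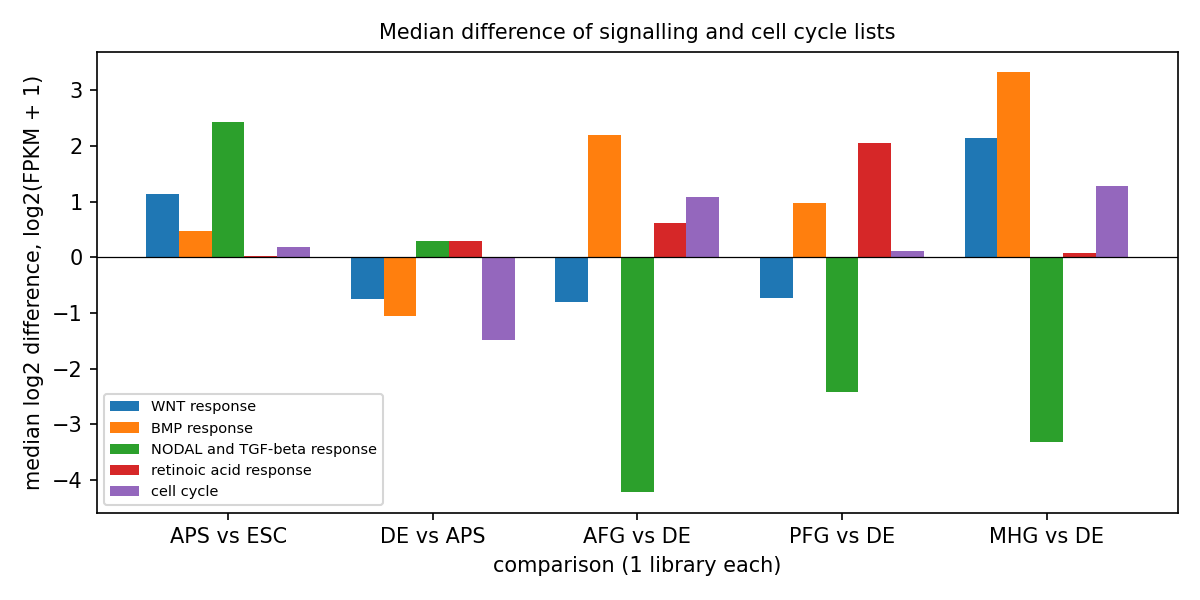
Median log2(FPKM + 1) difference of 5 fixed lists in the 5 comparisons along the differentiation, 1 bar per list, with 1 library on each side. Against DE, the NODAL and TGF-beta response was at −4.21 in AFG, −2.42 in PFG and −3.31 in MHG. In the same order, the BMP response was at 2.21, 0.98 and 3.32, and the retinoic acid response at 0.61, 2.06 and 0.09. The cell cycle was at −1.49 in DE against APS.

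The 3 day 7 libraries were then set against each other. PFG against AFG had 980 genes higher and 763 lower among 13641, or 616 and 469 with a pseudocount of 3. HOX paralogues 1 to 4 had the highest median, 1.36, above all random lists, with all 7 measured members higher, and the value was 0.61 with a pseudocount of 3. No member reached 1 FPKM in AFG, so no measured one could have been lower in PFG. Hepatic genes were higher for 8 of 10 and lower for 1, RBP4 (26.1 FPKM in AFG and 0.09 in PFG), and posterior foregut genes were higher for 8 of 12. IGFBP6 stood at 5.60 FPKM in AFG and 534 in PFG, GJA4 at 0.04 and 111, and CDKN2B, which inhibits the cyclin-dependent kinases CDK4 and CDK6, at 0.36 and 83.2. Its span overlaps 1 other row. Retinoic acid response genes were higher for 9 of 13 and lower for 1, CYP26C1 (31.1 FPKM in AFG and 0.02 in PFG). The anterior foregut list had the lowest median, −2.70, below all random lists, with 11 of 12 lower. Cell cycle genes had a median below all random lists, although 1 of 17 was 2-fold lower. NODAL and TGF-beta response genes were higher for 8 of 13 and lower for 2 in PFG, with NODAL at 10.2 FPKM against 0.47.

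MHG against AFG had 721 genes higher and 1108 lower among 13519, and a pseudocount of 3 gave 699 lower. Rescaling to the mean sum gave 627 and 1299, a share of 32.6% higher against 39.4%. Median-ratio scaling gave 720 and 1088, a share of 39.8%. HOX paralogues 5 to 9 had the highest median, 3.20, above all random lists, with 14 of 15 members higher. No member reached 1 FPKM in AFG, so no measured one could have been lower in MHG. WNT response genes were higher for 11 of 14, with AXIN2 at 3.49 FPKM in AFG and 83.6 in MHG and FZD10 at 0.04 and 41.0, and BMP response genes for 7 of 11, with ID1 at 256 and 693. The anterior foregut list had the lowest median, −2.48, below all random lists, with 11 of 13 lower and 1 higher. PKDCC stood at 334 FPKM in AFG and 2.12 in MHG, and OTX2 at 164 and 3.18.

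MHG against PFG had 1067 genes higher and 1551 lower among 13592, or 709 and 986 with a pseudocount of 3. When each library was rescaled to the mean sum the counts were 783 and 1922, and the share of higher genes was 28.9% against 40.8%. Median-ratio scaling gave 937 and 1667, a share of 36.0%. HOX paralogues 5 to 9 had the highest median, 3.17, above all random lists, with 13 of 14 measured members higher, while paralogues 1 to 4 divided into 5 higher and 2 lower, with HOXB1 at 18.3 FPKM in PFG and 0.71 in MHG. Mid-hindgut genes were higher for 9 and lower for 2 of 14, WNT response genes higher for 11 and lower for 1 of 14, and cell cycle genes higher for 11 of 17, with CCNB1 at 52.0 and 134. The retinoic acid response list had the lowest median, −2.42, below all random lists, with 10 of 12 lower and 1 higher, and all 9 measured hepatic genes were lower. NPPB stood at 462 FPKM in PFG and 1.55 in MHG, and HSPB8 at 151 and 1.77.

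**Figure D3:**
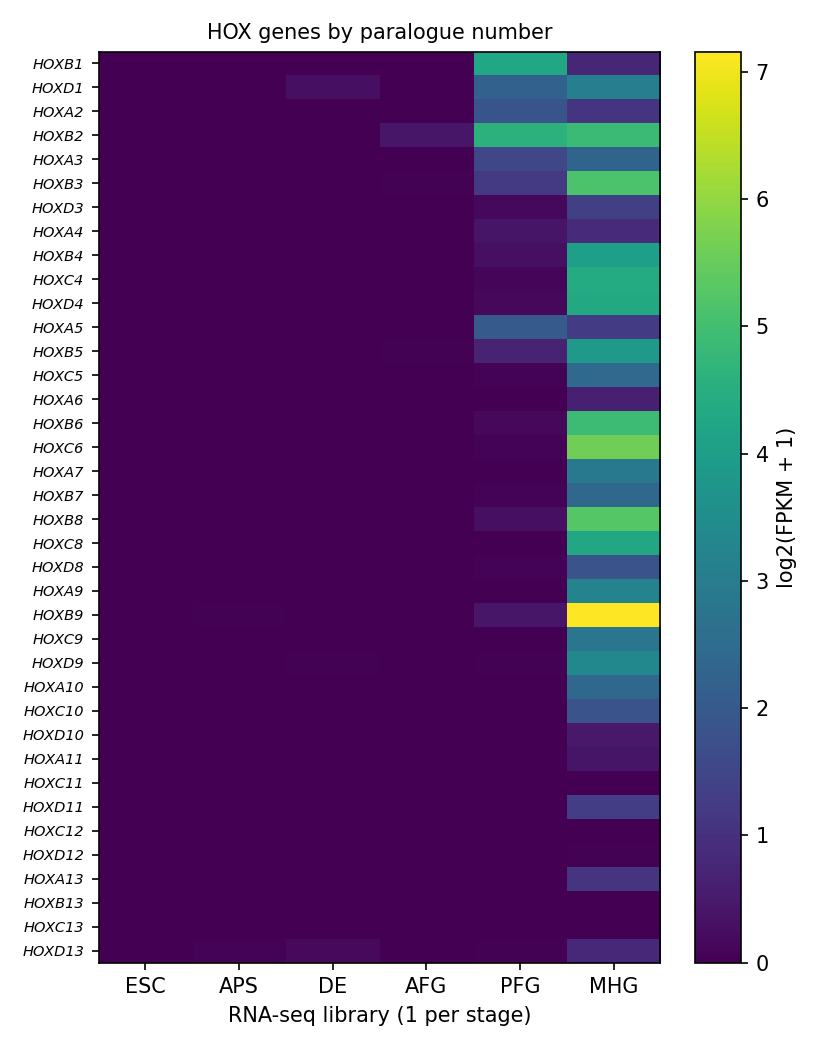
Expression of 38 HOX genes of the fixed lists in the 6 libraries as log2(FPKM + 1) by colour, ordered by paralogue number from top to bottom. HOXB2 stood at 23.4 FPKM in PFG and HOXB9 at 142 in MHG, and none of these genes reached 1 FPKM in ESC, APS, DE or AFG.

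The number of genes marking a library, at least 4-fold above each of the other 5, was 63 for ESC, 25 for APS, 88 for DE, 63 for AFG, 108 for PFG and 82 for MHG. ESC was marked by HES3, IDO1, MT1G and SOX2, and APS by DKK4 (921 FPKM), FGF4 (19.2) and PDGFRA (22.6). Of the 25 APS genes, 10 had a deposited interval above those of all other libraries. DE was marked by LEFTY2, LEFTY1, ERBB4 (38.8 FPKM) and STC1 (357). AFG was marked by VGLL2, FOXI2 (52.5 FPKM) and PAX1. PFG was marked by IGF2, IGFBP3, TTR, CYP26B1 and SPP1 (679 FPKM), and MHG by CDX2, HOXB9, MSX1, WNT5A (84.3 FPKM) and TBX3. With a pseudocount of 3 the counts were 32 for ESC, 56 for DE, 36 for AFG and 69 for PFG.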

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

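The tests of library scaling and of carried-over DE and ESC cells were chosen after the results they bear on had been seen.

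The WNT response list went opposite ways among the day 7 libraries set against DE. Its median was 2.14 in MHG, −0.80 in AFG and −0.72 in PFG, each outside the middle 95% of matched random lists. The difference between these effects was not tested, since each stage had 1 library and all 3 share the DE library.

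Cell cycle genes were lower in DE than in APS, with a median of −1.49. Library scaling does not account for it, since the median after median-ratio scaling was −1.34. A list of 20 DNA replication genes, none of them in the cell cycle list, had a median of −1.10, below all random lists. A candidate explanation is lower expression of S-phase genes in DE, a hypothesis found and tested on the same 2 libraries. Both lists are tied to the same process. The share of cells in S phase was not measured. A difference in culture density or in that DE culture alone was not tested.

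POU5F1, TDGF1, NODAL and CER1 stood at 28.0, 14.2, 10.2 and 137 FPKM in PFG, above AFG and MHG, and DE cells carried over without change would have to make up 37.1%, 2.19%, 5.20% and 1.82% of the PFG RNA to supply them, gene by gene. Of 58 other genes of 100 FPKM or more in DE and at least 4-fold above AFG and MHG, chosen without regard to PFG, 38 lay below 37.1% of their DE level by their upper bound, 9 (15.5%) below 1.82% and 6 at least 2-fold below 1.82%, among them LEFTY2 (0.168%) and FGF17 (0.271%). Unchanged DE cells would bring all of these genes, which argues against them as the source, by a bound of 5 genes 2-fold below that was set after these values were seen, while an earlier bound of 25% below the lowest need was not met, and DE cells that had lost some genes stay open. No share of ESC RNA would supply NODAL and CER1, since the lower bound of NODAL in PFG was 325% of its upper bound in ESC and CER1 exceeded its ESC level further. Of 21 such ESC genes, copies of POU5F1 left out, 3 lay below the 2.81% that POU5F1 needs by their upper bounds. These were MT1G (0.44%), RARRES2 (1.54%) and THY1 (1.96%). Unchanged ESC would bring these genes too, so the 3 go against that source, but only 1 lay at least 2-fold below, short of the bound of 5 genes. By that bound, ESC as a source of POU5F1 and TDGF1 stays open, and no biological explanation was tested.

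CDKN1A and MDM2 stood at 129 and 59.7 FPKM in PFG, against 70.4 and 15.6 in AFG and 77.4 and 17.4 in MHG. Library scaling does not account for MDM2, which differed by 1.95 between PFG and AFG after median-ratio scaling. A list of 21 other p53 targets, written before its values were seen, had a median of 0.60 for PFG against AFG, above all random lists, with 6 members 2-fold higher and none lower. The list was not raised in PFG alone. Against the same DE library its median was 0.55 in AFG, 1.19 in PFG and 0.63 in MHG. In that order, 35, 0 and 26 of the 10000 random lists lay at or above these medians. CDKN1A was less than 2-fold higher in PFG than in AFG or MHG, and the scaling test did not cover it. A candidate explanation is a wider p53 target response that was larger in PFG than in AFG or MHG, as a hypothesis from 1 library per stage. Whether the larger response in PFG came from the medium or from this culture was not tested.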

How the results depend on the processing

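Keeping failed rows, rescaling to the mean library sum and taking list medians over measured members alone were chosen after the data had been seen. Counts given here lie over 1.5 times from the main value, and list medians over 0.5 log2 units from it. No list median of at least 0.5 in size, and no named gene of at least 1, changed sign under any alternative run. The 16 counts of higher and lower genes stayed within 1.5 times of their main values under all 3 rescalings, a pseudocount of 0.1, no FPKM filter, intervals that do not overlap, summed rows and failed rows kept. With the 4-fold threshold the counts were 251 higher and 210 lower for APS against ESC, 352 and 146 for DE against APS, 379 and 481 for AFG against DE, 408 and 391 for PFG against DE, 372 and 589 for MHG against DE, 306 and 227 for PFG against AFG, 280 and 357 for MHG against AFG, and 273 and 468 for MHG against PFG, fewer by construction. With a pseudocount of 3, which shrinks the differences of low genes, 592 genes were lower for APS against ESC, 816 higher and 600 lower for DE against APS, 819 higher for AFG against DE, 826 higher for PFG against DE, 948 higher for MHG against DE, 616 higher and 469 lower for PFG against AFG, 699 lower for MHG against AFG, and 709 higher and 986 lower for MHG against PFG. An FPKM minimum of 5 gave 759 lower for APS against ESC, since fewer genes enter. Genes marking a library with a 2-fold margin numbered 236 for ESC, 69 for APS, 274 for DE, 182 for AFG, 267 for PFG and 173 for MHG, more by construction. With a pseudocount of 3 they numbered 32 for ESC, 56 for DE, 36 for AFG and 69 for PFG. For APS, 10 remained with intervals that do not overlap, and for AFG rescaling to a sum of 1000000, which also shrinks the weight of the pseudocount and of the FPKM minimum, gave 102, where the mean sum gave 68.

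Over the 208 medians of a list in a comparison, an FPKM minimum of 5 moved 82 of the 179 it could give, measured members alone 72 of 194, a pseudocount of 0.1 moved 45, one of 3 moved 25 and a sum of 1000000 moved 11, while median-ratio scaling, the mean sum, no FPKM filter (which leaves these medians as they are) and summed rows moved none. The values that follow cover only the list with the highest and the list with the lowest median in each comparison. A pseudocount of 0.1 gave 7.59 for the primitive streak in APS against ESC, 3.52 for anterior foregut and −4.78 for the NODAL and TGF-beta response in AFG against DE, −3.91 for the primitive streak in PFG against DE, −4.21 for definitive endoderm in MHG against DE, −3.68 for anterior foregut and 3.91 for HOX paralogues 1 to 4 in PFG against AFG, −4.00 for anterior foregut and 6.35 for HOX paralogues 5 to 9 in MHG against AFG, and 5.93 for HOX paralogues 5 to 9 and −3.85 for the retinoic acid response in MHG against PFG. In the same order, a pseudocount of 3 gave 5.07, 1.71, −2.82, −2.70 and −2.85, then 2.22 for the BMP response in MHG against DE, −1.87 and 0.61 in PFG against AFG, 1.90 for HOX paralogues 5 to 9 in MHG against AFG and 1.90 in MHG against PFG, and −1.77 for the retinoic acid response. An FPKM minimum of 5, which drops silent members, gave 3.46 for anterior foregut in AFG against DE, −5.06 for the primitive streak in PFG against DE, −4.66 for definitive endoderm and 4.50 for the BMP response in MHG against DE, −3.68 for anterior foregut and 4.25 for HOX paralogues 1 to 4 in PFG against AFG, −3.48 for anterior foregut and 4.04 for HOX paralogues 5 to 9 in MHG against AFG, and 3.79 for HOX paralogues 5 to 9 and −2.96 for the retinoic acid response in MHG against PFG. Measured members alone gave −5.06 for the primitive streak in PFG against DE, −3.33 for anterior foregut and 2.22 for HOX paralogues 1 to 4 in PFG against AFG, −3.26 for anterior foregut in MHG against AFG, and −2.96 for the retinoic acid response in MHG against PFG. Rescaling to 1000000 gave 2.02 for HOX paralogues 1 to 4 in PFG against AFG, 3.94 for HOX paralogues 5 to 9 in MHG against AFG, and −3.06 for the retinoic acid response in MHG against PFG, where the mean sum gave 1.44, 3.15 and −2.54. Median-ratio scaling moved the median difference of all genes from −0.07 to 0.06 in DE against APS, and rescaling to the mean sum moved it from −0.03 to −0.14 in MHG against AFG and from 0.02 to −0.15 in MHG against PFG. Depth limits low genes most, whose deposited bounds are the widest. No paired analysis was possible because each stage had 1 library, and no library could be left out.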

Other observations

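The 9 lists described here were written after the main results had been seen, and genes named from them were chosen after their values were seen. Metallothionein genes were lower at each of the first steps, for 6 of 7 measured members in APS against ESC and for 6 of 6 in DE against APS. MT1X stood at 119 FPKM in ESC, 40.9 in APS and 1.65 in DE, and MT2A at 85.5, 26.6 and 2.01. At day 7 MT1X was at 16.8 in AFG, 5.65 in PFG and 39.3 in MHG. Reads of this family of similar genes may not be fully separable, so single members are uncertain. The list median of −1.99 in DE against APS lay below all random lists.

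Genes of the IGF system were higher in PFG than in DE for 7 of 10 measured members. IGFBP2 stood at 194 FPKM in DE and 862 in PFG, and IGFBP5 at 1.49 and 95.6. Basement membrane genes were higher than in DE for 6 of 10 in PFG, 5 in AFG (with 1 lower) and 4 in MHG, with medians of 1.44, 0.74 and 0.66. In DE and PFG HSPG2 (perlecan) stood at 33.9 and 83.6 FPKM and LAMA1 at 16.8 and 80.5. Of the 10 genes of the serine and ATF4 list, 7 were lower in MHG than in DE, including ASNS (133 and 26.1 FPKM), CHAC1 (31.4 and 2.26) and VLDLR (42.9 and 1.37). Its members PHGDH (227 and 132 FPKM), PSAT1 (208 and 135) and SHMT2 (165 and 85.7) were lower by less than 2-fold. Genes of glycolysis and hypoxia were lower for 6 and higher for 1 of 12 in MHG against DE, with a median of −0.99, below all random lists. The lower ones were ADM, BNIP3, PFKP, VEGFA, PDK1 and SLC2A3. ALDOA (442 FPKM in DE and 431 in MHG), ENO1 (1007 and 966) and LDHA (140 and 143) stayed near their DE levels. Against the same DE library 5 were lower and 1 higher in AFG, and 4 and 3 in PFG, with medians of −0.53 and −0.43. DNA replication genes were lower in PFG than in AFG for 6 of 20, and higher in MHG than in PFG for 14 of 20. No cholesterol synthesis gene of 13 differed 2-fold in any comparison. Yolk sac endoderm genes were higher for 4 and lower for 1 of 8 measured in PFG against DE, with VTN at 1.30 and 59.1 FPKM, and 2 of their members also stand in the hepatic list. The list median there was 0.06, inside the middle 95% of random lists. In AFG against DE it was 0.41, above that range, with 3 higher and 2 lower of 9. Among the p53 targets, GDF15 was at 10.6 FPKM in AFG, 290 in PFG and 11.5 in MHG.

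Rows for very short genes held a sizeable part of the summed FPKM. The 1372 rows spanning under 200 bases made up 13.8% of it in ESC, 12.8% in MHG and 7.92% in PFG. These rows therefore weigh on any rescaling by the library sum. MIR1282, a microRNA row of 101 bases on chromosome 15, was the row with the highest FPKM within AFG (5453) and within MHG (4880). It stood at 5353 in PFG and at 3820 in ESC, 3907 in APS and 4008 in DE. FPKM is per kilobase, so few fragments can give so short a row a high value.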
